A study of Mus musculus with 99 samples.

How the data were processed

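The measurements were single-cell RNA sequencing profiles of 99 plasma cells from the bone marrow of wild-type, unstimulated mice, with 1 library per cell. Per the labels' protocols, RNA was extracted on a C1 array, a microfluidic capture device, in the presence of spike-in RNA, and libraries were made with the Nextera XT kit, which fragments cDNA with a transposon. The labels put all 99 cells in 1 group and name no animal, so the series was treated as 1 sample of cells. No p-value or standard error was computed across cells, because cells are not replicates.

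The authors deposited whole-number read counts per Ensembl gene and cell in 2 tables. The submitters' processing notes name Trim Galore, STAR 2.4 and featureCounts and the mm10 build. The roles and order of these tools, the strand setting, the treatment of multi-mapping reads and the annotation release are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart. Reads shared by near-identical immunoglobulin genes, such as variable genes of 1 family or the IgG constant genes, could have been dropped or assigned to a neighbour. No molecular identifiers are described, so reads are not independent molecules, and all intervals and limits for a count of 0 cover counting error only.

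The cell titles had 2 forms, and each form had its own table. The letter_number form (A1 to H7) covered 60 cells in a table without spike-in genes, and the decimal form (such as 11.1) covered 39 cells in a table with 92 spike-in genes. The labels do not say what the codes mean or whether the forms were separate runs. Differences between classes were therefore computed pooled and within each form. Both tables listed the same 46078 genes. Symbols and GRCm38 coordinates came from GENCODE release M21 and a table of gene names. A symbol was found for 45143 genes, and the other 935 held 0.0203% of reads. A gene was counted as immunoglobulin by its annotated type or symbol (429 genes).

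A cell passed with at least 10000 reads on genes that were neither immunoglobulin nor spike-in, at least 500 such genes with a read, and at least 3 plasma cell identity genes with a read. All 99 cells passed. The isotype class of a cell was the heavy-chain constant class with at least 80% of its heavy-chain constant reads, with a minimum of 50 such reads. Ighm and Ighd stood for IgM, Igha for IgA, Ighg1, Ighg2b, Ighg2c and Ighg3 for IgG, and Ighe for IgE. Other cells were left unclassed. No doublet caller was run, and doublets that met the class share were not removed. The IgM-class cell F6 kept 15.8% IgG reads and a second heavy-chain variable gene at 17.8%, but was too shallow for the shares. The IgM-class cells H4, E4 and C4, the IgG-class cell B2 and the IgA-class cell 39.3 stayed in the shares. Their second heavy-chain variable gene held 11.4% to 31.7% of heavy-chain variable reads. Heavy-chain constant genes define the classes and are not reported as differences.

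For detection, the reads of each cell on non-immunoglobulin genes were thinned with a fixed seed to 630000, which is the 20th percentile over cells rounded down to a multiple of 10000. A gene was detected with at least 5 thinned reads. The 20 shallower cells were left out of shares, which left 35 of 41 IgM-class, 25 of 34 IgA-class and 12 of 17 IgG-class cells, and all 7 unclassed cells. Shares carry exact (Clopper-Pearson) 95% intervals. The limit for a share of 0 is 3 cells, or 8.57% of 35 cells, 12% of 25 cells and 25% of 12 cells. Expression levels are RPM, reads per 1000000 non-immunoglobulin, non-spike-in reads, unthinned, over all cells of a class. The values of 23 gene lists are the mean, over the detected genes of a list, of the difference in share of cells. The percentile of a list is its rank among 10000 random lists of the same size matched on pooled share, as a description of these cells.

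The lists covered plasma cell identity; chemokine and trafficking receptors, adhesion molecules, and survival receptors and apoptosis regulators, together called niche lists; transcription factors, the unfolded protein response and secretion, B cell identity and antigen presentation, proliferation, interferon response, the TGF-beta and retinoic acid pathway, immunoregulatory molecules, Fc, Toll-like and pattern receptors, metabolism and nutrient transport, and autophagy; and the immediate early response. The other 8 held markers of T cells, NK cells, myeloid cells, erythroid cells, megakaryocytes and platelets, dendritic cells, stromal and endothelial cells, and B cell precursors. Named genes were chosen by size: up to 10 genes per direction with the largest pooled difference, of at least 30 percentage points pooled and at least 15 points in the same direction within each title form with at least 5 cells of both classes. Genes of the niche and state lists with at least 25 points, all identity genes, and the 3 most often detected genes of each list were added. Immunoglobulin, ribosomal protein, mitochondrial and predicted genes were not eligible for the first part. The values of 1 adhesion gene that met the rule are not reported here. Only the comparison of IgG with IgM had 5 cells of both classes in a form, the letter_number form. The lists, rules, comparisons and a first set of alternatives were fixed before the data were examined.

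The share calculation was tested on simulated cells with 13214 genes per comparison, of which 200 had a difference of 50 points. The mean recovered difference was 50.1 points for IgG minus IgM, 48.9 for IgA minus IgM and 48.7 for IgA minus IgG. A difference of 30 points was reached by 91.5%, 94.5% and 90.5% of these genes, and by 1.44%, 0.277% and 1.98% of the unaltered genes. Among unaltered genes in the same range of pooled share as the altered ones, it was reached by 2.53%, 0.394% and 3.57%. The simulated cells had no difference between title forms, so these rates do not cover comparisons in which class and form overlap.

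The alternatives fixed in advance were a class share of 50% or 95%, no cell filter or a stricter one (50000 reads and 1000 genes), no thinning, detection at 1 or 20 reads or at 10 RPM, genes detected in at least 10% of cells, each title form alone, and the mean of log2(RPM + 1). Those added after seeing the data were equal weight for the title forms, thinning to 250000 reads (which keeps every cell), and a read spill limit. That limit required detection to exceed 0.2% of the reads of a gene in letter_number cells sharing the letter or number. Leaving out Jchain before thinning, leaving out cells with a second heavy-chain variable gene at 10% or more, leaving out the decimal cell 22.3 or, for proliferation, each IgG-class cell in turn, running all alternatives on the other lists, and an agreement between forms from 3 cells per class were also added. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.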

Results

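Gene expression was measured in 99 single plasma cells, the antibody-secreting end stage of the B lineage, taken from the bone marrow of unstimulated mice. The title of the series asks about plasma cell subsets defined by antibody isotype and their needs in the marrow niche. Reads on genes numbered 2086118 per cell at the median (575982 to 12304520), with a median of 2041851 in the 60 letter_number cells and 2143987 in the 39 decimal cells. Immunoglobulin genes held 56.9% of reads at the median (19.2% to 77.2%). The remaining 868315 reads at the median (265087 to 6862770) covered 3803 other genes per cell. Mitochondrial genes held 1.65% of the other reads at the median. In the decimal cells, where spike-ins are listed, there were 1.68 gene reads per spike-in read at the median (0.18 to 2.86).

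The cells carried the transcripts of the plasma cell program. Xbp1, a transcription factor of secretory cells, Mzb1, a chaperone of antibody assembly, and Jchain, the joining chain of polymeric antibodies, were each detected in 79 of 79 thinned cells (100%, 95.4% to 100%). Median levels, in reads per 1000000 non-immunoglobulin reads (RPM), were 1459 RPM for Xbp1, 2892 RPM for Mzb1 and 83116 RPM for Jchain. The receptors for the survival factors APRIL and BAFF were frequent, with Tnfrsf13b (TACI) in 70 cells (88.6%) and Tnfrsf17 (BCMA) in 56 cells (70.9%), and the costimulatory receptor Cd28 was detected in 55 cells (69.6%). Among adhesion molecules, Cd44 was detected in 79.7% of cells, Cd24a in 68.4% and Cd47 in 64.6%. Chemokine receptors were rarer, with Cxcr4 in 26 cells (32.9%, 22.7% to 44.4%), Ccr10 in 14 (17.7%) and Ccr9 in 8 (10.1%). Secretory genes Hsp90b1, Herpud1 and Sec11c and the interferon-responsive Ly6e were detected in every thinned cell. So was the antigen-presentation gene Cd74.

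Markers of other marrow cells were low. The summed level per cell had a median of 0 RPM for T cell, NK cell, erythroid, and megakaryocyte and platelet markers, 0.717 RPM for stromal and endothelial markers and 0.772 RPM for myeloid markers. The most often detected gene of each of these lists was Pecam1 in 17 cells (21.5%), S100a9 in 11 (13.9%), Lck in 7 (8.86%), Gzma in 3, Itga2b in 3 and Hbb-bs in 1 of 79 cells. The myeloid markers Ngp and Ltf were each detected in 10 cells (12.7%). Dendritic cell markers reached 1606 RPM, from Cst3 (98.7% of cells) and Tcf4 (92.4%), which are not limited to dendritic cells. B cell precursor markers reached 227 RPM, mainly from Cd24a and Vpreb3 (32.9%). Myeloid markers had a median of 14.1 RPM in decimal cells and 0 RPM in letter_number cells.

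Heavy-chain constant reads placed 92 of the 99 cells in 1 class, as the plot of heavy-chain reads per cell shows. The constant genes lie side by side on chromosome 12, from Igha (113254830 to 113260236) to Ighm (113418558 to 113422730). The IgM class held 41 cells (41.4%, 31.6% to 51.8%), the IgA class 34 (34.3%, 25.1% to 44.6%) and the IgG class 17 (17.2%, 10.3% to 26.1%). No cell was in the IgE class (0 of 99, which allows up to 3.03%), and 7 cells (7.07%, 2.89% to 14.03%) had reads of 2 classes and stayed unclassed. Within the IgG class, Ighg2b led in 11 cells, Ighg1 in 3, Ighg2c in 2 and Ighg3 in 1. The leading class held 99.7% of heavy-chain constant reads at the median, and at least 84.2%. The class sizes differed between the title forms. Letter_number cells were 61.7% IgM, 5% IgA and 21.7% IgG, and decimal cells were 10.3% IgM, 79.5% IgA and 10.3% IgG. Comparisons with the IgA class are therefore largely comparisons between title forms.

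**Figure D1:**
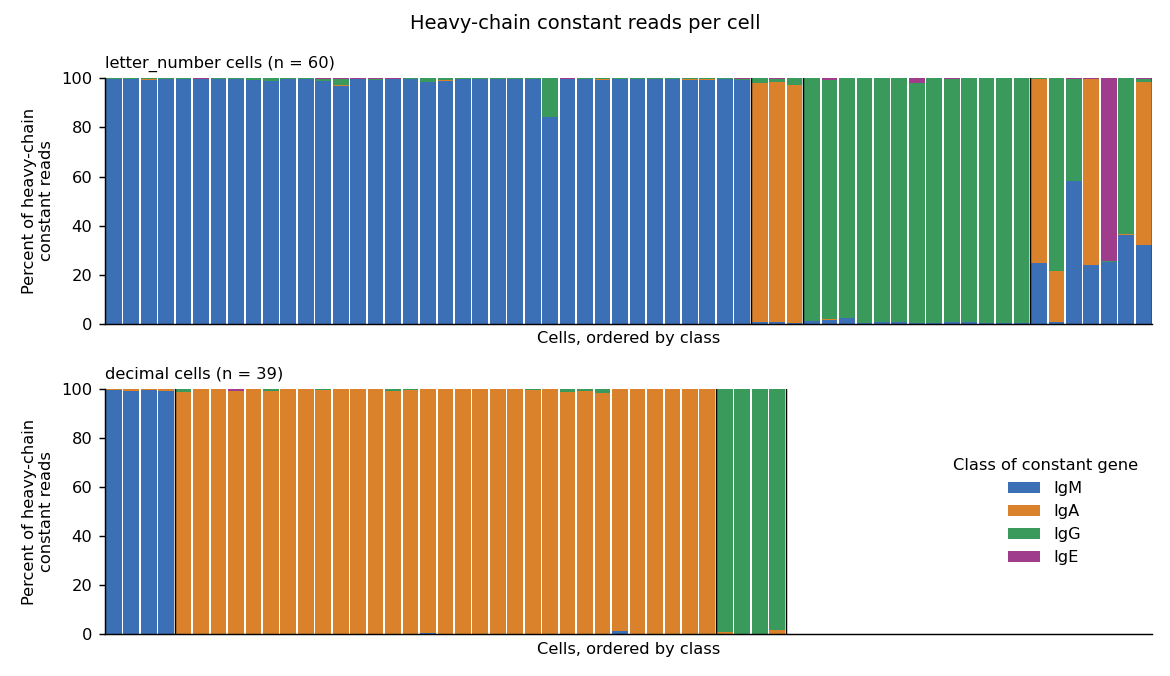
Percent of heavy-chain constant reads on IgM, IgA, IgG and IgE genes in each of 60 letter_number cells and 39 decimal cells, 1 bar per cell, ordered by class. Most bars are of 1 color. The 7 unclassed letter_number cells show 2, as does the IgM-class cell F6 (84.2% IgM and 15.8% IgG).

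Ighe was the leading constant gene of the unclassed cell D7, with 74.7% of its heavy-chain constant reads, beside 25.3% of the IgM class. Lower Ighe counts in the other letter_number cells followed the letter and number of the title, as the map of Ighe reads shows, except for 14324 reads in cell C2. Variable genes strongly read in 1 letter_number cell also appeared, at a median of 0.0467% of its reads, in cells sharing its letter or number, so low counts in these cells can include reads of another cell. Among decimal cells, Igkv9-124, Igkv4-57-1, Igkv12-46 and Igkv12-44 had medians of 31 to 51 reads in cells sharing the last digit of their source cell. In the remaining decimal cells the medians were 0 or 1. The other variable genes checked there had medians of at most 6 reads in cells sharing that digit. The read spill limit was not applied to decimal cells.

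**Figure D2:**
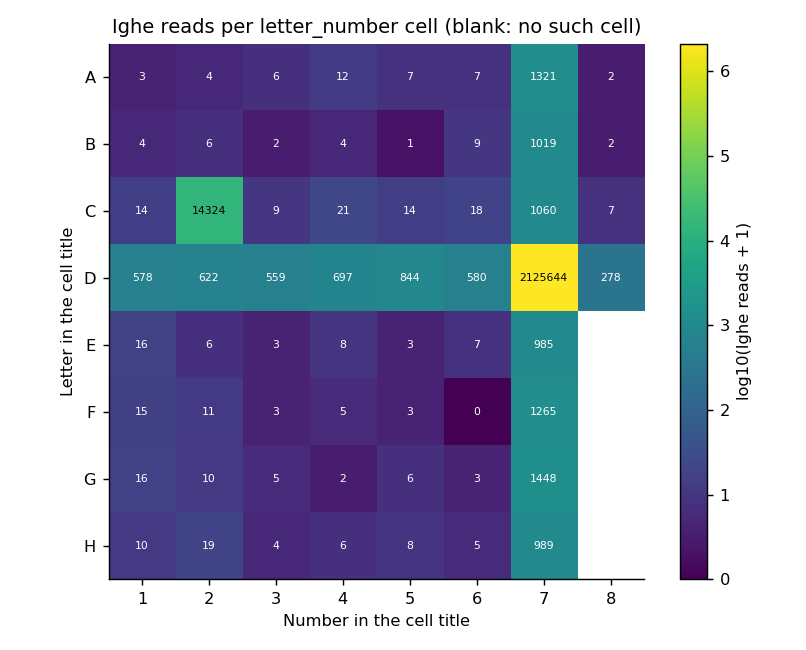
Ighe reads in each letter_number cell as log10(reads + 1), placed by the letter and number of its title, with blanks where no cell has that title. Cell D7 has 2125644 reads, and the 14 cells sharing its letter or number have 278 to 1448.

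Title forms were also compared within a class. Thinned to 250000 reads, the same class differed between forms by a mean absolute 18.2 percentage points per gene for IgM, 18.3 for IgA and 19.6 for IgG. The signed means, letter_number minus decimal, were 9.14, 2.41 and 2.76 points. The smaller form had 4, 3 and 4 cells, so counting alone adds to the absolute values. No value for forms without a difference was computed, so their size does not show a form effect. Across 4933 genes, the class differences in the letter_number cells and in the decimal cells had Pearson's r of 0.0921 and Spearman's rho of 0.0915 for IgG minus IgM. For IgA minus IgM r was 0.0580 and rho 0.0373, and for IgA minus IgG r was 0.0915 and rho 0.0674. These 3 correlations run across genes, which are not independent replicates, and rest on as few as 3 cells of a class in a form.

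Jchain, which links antibody units in secreted IgM and IgA, was highest in the IgA class and lowest in the IgG class (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891). The median was 171947 RPM in 34 IgA-class cells (83116 to 363855), 65580 RPM in 41 IgM-class cells (269 to 206251) and 11982 RPM in 17 IgG-class cells (2590 to 72437). The IgG median was lower than the IgM median 5.47-fold pooled, 6.44-fold within letter_number cells and 3.54-fold within decimal cells. The IgA median was 14.4-fold the IgG median pooled, 13.3-fold within letter_number cells and 3.86-fold within decimal cells. IgA and IgM differed 2.62-fold pooled and 2.07-fold within letter_number cells, but 1.09-fold within decimal cells.

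**Figure D3:**
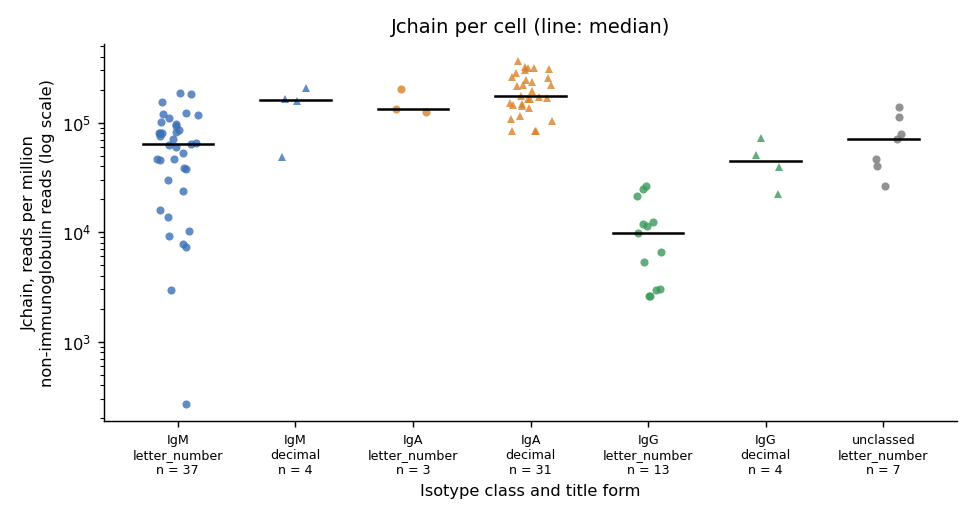
Jchain level of each cell in RPM on a log axis, by isotype class and title form, with a line at each median. In letter_number cells the medians are 63856 (IgM, n = 37), 132049 (IgA, n = 3) and 9912 (IgG, n = 13).

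The comparison of IgG-class with IgM-class cells addressed whether these isotypes differ in receptors and state. Proliferation genes were detected more often in IgG-class cells, on average in 39.2% of 12 cells against 15.3% of 35 IgM-class cells, a difference of 23.9 points. The difference was 27.3 points within letter_number cells (9 against 32) and 17.2 within decimal cells (3 against 3). The decimal value rests on cell 22.3, which had 21 of the 31 genes. Without it the difference was -2.69 points within decimal cells and 21.4 pooled. The difference was at least 25 points for 15 of the 31 genes and in no gene lower by that size, and the list lay at percentile 100 of random lists. Mki67, a marker of cycling cells, was detected in 8 of 12 IgG-class cells (66.7%, 34.9% to 90.1%) and 6 of 35 IgM-class cells (17.1%, 6.56% to 33.6%), and unthinned in 52.9% and 31.7%. Rrm2, which makes DNA precursors, was detected in 8 and 3 cells, the replication factor Mcm3 in 6 and 2, and the mitotic genes Ccna2, Ccnb2 and Nusap1 each in 5 and 0. An IgG-class cell had 8 of the 31 genes at the median (2 to 28) and an IgM-class cell 4 (1 to 13). With every cell kept at 250000 reads, the median was 4 genes in 17 IgG-class and 4 in 41 IgM-class cells. The proliferation difference was 16.1 points without thinning and 14.9 with all cells kept by thinning to 250000 reads. IgG-class cells also had more genes of any kind detected after thinning, 2322.5 against 2188 at the median of 12 and 35 cells. Genes with at least 1 unthinned read, over all 17 and 41 cells, numbered 4186 against 4354. The threshold and the cells differ between these 2 measures, so the change is not an effect of thinning alone.

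**Figure D4:**
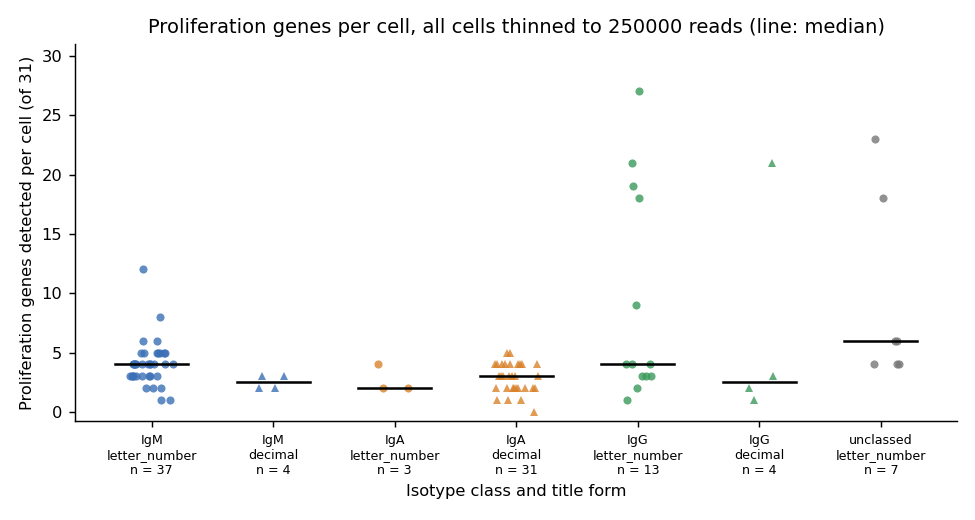
Number of the 31 proliferation genes detected in each cell after thinning every cell to 250000 reads, by isotype class and title form, with a line at each median. In the IgG class 5 of 17 cells have 15 or more, up to 27, and the highest IgM-class cell has 12.

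Genes of B cell identity and antigen presentation were detected less often in IgG-class cells, on average in 29.5% against 39.9%, a difference of -10.4 points (-12.3 in letter_number and 0 in decimal cells). No gene of the list was 25 points higher and 5 of 24 were 25 points lower. Ms4a1, which encodes the B cell surface protein CD20, was detected in 4 of 12 IgG-class cells (33.3%, 9.92% to 65.1%) and 26 of 35 IgM-class cells (74.3%, 56.7% to 87.5%), although with detection at 1 read its difference was 5.95 points. The class II gene H2-Eb1 was detected in 50% and 77.1% of cells pooled, but its IgM-class share was 81.25% in letter_number and 33.3% in decimal cells. Blk, a B cell kinase, was detected in 0 and 11 cells. Fc, Toll-like and pattern receptors differed by -5.33 points (-7.31 and 4.44 within forms), with the IgM receptor Fcmr in 1 and 13 cells.

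Of the niche lists for IgG minus IgM, adhesion and survival lay low among matched random lists, and chemokine receptors lay near the middle when pooled. Pooled percentiles were 2.54, 0.88 and 51.51, in that order, with random medians of 3.58, 2.66 and 1.39 points. Within letter_number cells the percentiles were 0.82, 6.09 and 26.96. Chemokine and trafficking receptors differed by 1.43 points (0.116 and 8.33 within forms), adhesion molecules by -3.13 (-4.22 and 11.7) and survival receptors and apoptosis regulators by -5.18 (-1.88 and -12.3). Cxcr4, the receptor for the marrow chemokine CXCL12 (chromosome 1, 128588199 to 128592293), was detected in 10 of 12 IgG-class cells (83.3%, 51.6% to 97.9%) and 12 of 35 IgM-class cells (34.3%, 19.1% to 52.2%). Its difference was 51.4 points within letter_number cells and 66.7 within decimal cells, the unthinned shares were 76.5% and 46.3%, and its median level was 12.6 and 4.16 RPM. Among the 12 detected receptors, Cxcr4 was the 1 to differ by 25 points. Bcl2, an inhibitor of apoptosis, was detected in 2 of 12 (16.7%, 2.09% to 48.4%) and 20 of 35 cells (57.1%, 39.4% to 73.7%), and Bax, which promotes apoptosis, in 2 and 18 cells. The glycoprotein Cd24a was detected in 91.7% and 65.7% of cells.

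**Figure D5:**
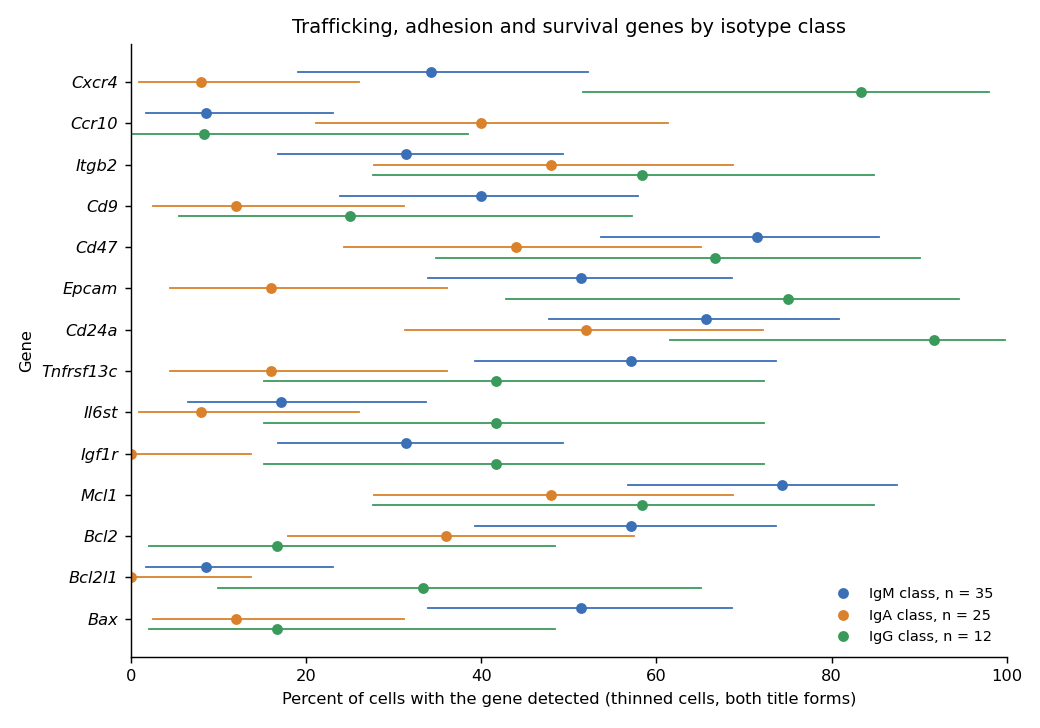
Percent of thinned cells of each isotype class (35 IgM, 25 IgA, 12 IgG) with each trafficking, adhesion or survival gene detected, with exact 95% intervals for counting error only. Cxcr4 is detected in 83.3% of IgG-class cells and 8% of IgA-class cells, at levels near the detection minimum.

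Secretory genes were near saturation in both classes, with 92.2% of IgG-class and 87.4% of IgM-class cells per gene of the unfolded protein response and secretion list (4.76 points, 5.09 in letter_number and 8.82 in decimal cells). Dnajb11, a chaperone of the endoplasmic reticulum, was detected in 12 of 12 and 26 of 35 cells, and Ern1, the stress sensor IRE1, in 8 and 13 cells. Interferon response differed by 6.05 points (6.08 and 9.26 within forms), metabolism and nutrient transport by 5.06 (5.36 and 23.2), plasma cell identity by 3.10 (3.37 and 5.13) and autophagy by 2.61 (4.78 and 1.85). Transcription factors differed by -3.02 points (-1.71 and -5.56). The forms had opposite signs for the TGF-beta and retinoic acid pathway (0.391 pooled, 2.16 and -4.76), the immediate early response (0.658, 6.15 and -21.6) and immunoregulatory molecules (-4.17, -7.34 and 11.1). Psat1, an enzyme of serine synthesis, was detected in 8 of 12 and 6 of 35 cells, and the autophagy receptor Sqstm1 in 3 and 24 cells. Outside the lists, the largest differences were Fkbp11, a peptide isomerase of secretory cells (11 of 12 against 9 of 35 cells, 65.95 points), and Supt16, a chromatin factor (63.6 points). Nrp1, the receptor neuropilin-1, differed by 55.2 points. S100a11, a calcium-binding protein, and Selenop, which encodes selenoprotein P, were each detected in 0 of 12 and 20 of 35 cells, and Tmsb4x, which encodes an actin-binding peptide, in 5 and 31 cells. Of 261 genes that differed by at least 30 points in letter_number cells, at 250000 reads, 66.9% of those with a decimal difference had the same sign there. Other-cell markers differed by 1.31 points (T cell), -1.43 (NK cell), -2.86 (erythroid), 5.48 (megakaryocyte and platelet) and 1.67 (stromal and endothelial), each with the pooled sign within letter_number cells and 0 within decimal cells. Myeloid markers differed by 1.69 points (-0.410 and -3.03 within forms), dendritic markers by -4.33 (-6.25 and 5.56) and B cell precursor markers by 6.90 (1.22 and 25). These differences have no replicate check, and the decimal values rest on 3 cells per class.

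IgA-class cells were compared with IgM-class cells for the same question. B cell genes were detected less often in IgA-class cells, on average in 24.2% of 25 cells against 39.9% of 35 cells, a difference of -15.7 points (-9.94 in letter_number and -10.0 in decimal cells). The list lay at percentile 0 of random lists pooled and at percentile 13.9 within letter_number cells, where the random median was -5.73 points, and 7 of its 24 genes were at least 25 points lower. Ms4a1 was detected in 1 of 25 IgA-class cells (4%, 0.101% to 20.4%) and 26 of 35 IgM-class cells, with differences of -78.1 and -28.8 points within the forms and unthinned shares of 5.88% and 70.7%. Fc, Toll-like and pattern receptors differed by -13.1 points (-12.5 and -7.88 within forms). Fcmr, the receptor for IgM, was detected in 0 of 25 and 13 of 35 cells, and Fcrla, an intracellular Fc receptor-like protein, in 8 and 23 cells.

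Among niche genes, Ccr10, a receptor for chemokines of mucosal tissue (chromosome 11, 101172997 to 101175443), was detected in 10 of 25 IgA-class cells (40%, 21.1% to 61.3%) and 3 of 35 IgM-class cells (8.57%, 1.80% to 23.1%), with 27.1 points within letter_number cells and 7.58 within decimal cells. The unthinned shares were 38.2% and 7.32%. The values within forms rest on 3 IgA-class letter_number cells and 3 IgM-class decimal cells, so a single cell can set their size. Ccr9, a receptor of gut homing, was detected in 20% and 5.71% of cells. Survival receptors and apoptosis regulators differed by -11.4 points (-16.5 and -6.86 within forms). Igf1r, a growth factor receptor, was detected in 0 of 25 and 11 of 35 cells, and Tnfrsf13c, the BAFF receptor, in 4 and 20 cells. Tnfrsf17 was detected in 84% of IgA-class and 62.9% of IgM-class cells. Adhesion molecules differed by -10.1 points, but by -10.9 and 5.83 within the forms, and chemokine and trafficking receptors by 1.10, but by -4.51 and 5.93. Matched random lists had medians of -9.80 points for adhesion (percentile 45.7), -2.95 for chemokine receptors (96.9) and -7.61 for survival (9.44). The adhesion protein Epcam was detected in 4 of 25 and 18 of 35 cells.

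The unfolded protein response and secretion list differed by -8.10 points (79.3% and 87.4%), with -6.68 in letter_number and -1.38 in decimal cells. Proliferation differed by -4.85 (-2.82 and -0.635 within forms), transcription factors by -7.24 (-5.42 and -5.61) and interferon response by -6.60 (-5.03 and -2.27). The forms had opposite signs for metabolism and nutrient transport (-9.07 pooled, -5.75 and 16.6), autophagy (-7.75, 4.17 and -1.43) and immunoregulatory molecules (-2.82, -6.60 and 5.66). Il10, which encodes a regulatory cytokine, was detected in 0 of 25 and 11 of 35 cells, with -34.4 points within letter_number cells and 0 within decimal cells. The small GTPase Arf6 was detected in 24 of 25 and 18 of 35 cells (50 and 28.8 points within forms), and Oosp1 in 0 of 25 and 22 of 35 cells (-62.5 and -66.7). Inpp4a, a phosphoinositide phosphatase, was detected in 6 and 32 cells (-57.3 and -77.3). Of 833 genes that differed by at least 30 points in letter_number cells, at 250000 reads, 55.6% of those with a decimal difference had the same sign there. Cd69, a marker of activation and tissue residence, differed by 40.6 points pooled but by -4.55 within decimal cells. IgA-class cells had fewer genes after thinning, with a median of 1624 against 2188, and random lists of these sizes had median differences below 0. Genes with at least 1 unthinned read, over all cells of each class, numbered 2865.5 against 4354. Within decimal cells the median genes after thinning were close, 1583 against 1625. Within letter_number cells they were 1766, from 3 IgA-class cells, against 2209. Myeloid markers differed by 12.1 points pooled and by -1.42 and -1.24 within the forms.

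Against IgG-class cells, IgA-class cells had Cxcr4 less often and, in the pooled cells, Ccr10 more often. Cxcr4 was detected in 2 of 25 IgA-class cells (8%, 0.984% to 26.03%) and 10 of 12 IgG-class cells, a difference of -75.3 points (-88.9 in letter_number and -57.6 in decimal cells). Its level in the IgA class was a median of 0 and a mean of 3.17 RPM, near the detection minimum. Ccr10 was detected in 10 of 25 and 1 of 12 cells, with 33.3 and 7.58 points within forms. These values rest on 3 IgA-class letter_number cells and 3 IgG-class decimal cells, so a single cell can set their size. Epcam was detected in 4 of 25 (16%, 4.54% to 36.1%) and 9 of 12 cells (75%, 42.8% to 94.5%), and Il6st, a subunit of the interleukin-6 receptor, in 2 and 5 cells. The chemokine and trafficking list as a whole differed by -0.333 points (-4.63 and -2.40 within forms), adhesion molecules by -6.98 (-6.67 and -5.83) and survival receptors and apoptosis regulators by -6.19 (-14.6 and 5.42). Random lists of the same sizes had lower medians, -13.4 points for adhesion (percentile 95.8) and -10.4 for survival (percentile 88.3), and IgA-class cells had fewer genes after thinning, 1624 against 2322.5. The median genes after thinning were 1766 and 2721 within letter_number cells and 1583 and 1996 within decimal cells.

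Proliferation genes were detected in 10.5% of IgA-class cells on average and 39.2% of IgG-class cells, a difference of -28.8 points (-30.1 and -17.8 within forms), with 21 of 31 genes at least 25 points lower. Without cell 22.3 the difference was -26.2 pooled and 2.05 within decimal cells. With every cell kept at 250000 reads, the median was 3 of the 31 genes in 34 IgA-class and 4 in 17 IgG-class cells. The unfolded protein response and secretion list differed by -12.9 points (-11.8 and -10.2), with 7 of 34 genes at least 25 points lower, among them Ern1 in 2 of 25 and 8 of 12 cells and Dnajb11 in 14 and 12 cells. Psat1 was detected in 0 of 25 and 8 of 12 cells. S100a11 was detected in 17 of 25 IgA-class cells (68%, 46.5% to 85.1%) and 0 of 12 IgG-class cells, with 66.7 and 68.2 points within forms, and Klf2, a transcription factor of lymphocyte trafficking, in 15 and 2 cells. Of 1397 genes that differed by at least 30 points in letter_number cells, at 250000 reads, 61% of those with a decimal difference had the same sign there. Myeloid markers differed by 10.4 points pooled (percentile 100) and by -1.01 and 1.79 within the forms. The letter_number values rest on 3 IgA-class cells and the decimal values on 3 IgG-class cells.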

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

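The test of index misassignment for cells with 2 heavy-chain classes was chosen after its result was seen, and the other tests here were set beforehand. No biological explanation was tested, since the labels give 1 group.

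Ighe reads appeared outside the class comparisons, since no cell was in the IgE class. The unclassed cell D7 had 2125644 Ighe reads, 74.7% of its heavy-chain constant reads. The 14 cells sharing its letter or number had a median of 914.5 (278 to 1448), or 0.0430% of the D7 reads, and the 45 others a median of 6. Variable genes with 100000 or more reads in a single cell were checked the same way. Their median ratio of reads in cells sharing the letter or number to reads in the rest, with 1 added to each, was 61, and 17 of 17 genes had a ratio of 5 or more. A ratio of 61 argues against free immunoglobulin RNA shared by all cells and is consistent with index misassignment between wells that share a plate row or column, while the 14324 Ighe reads in cell C2 stay unexplained.

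Reads of 2 heavy-chain classes were found in 7 cells, all letter_number, with second-class shares from 20.8% to 41.9%. Among them 6 of 7 had a second heavy-chain variable gene with at least 10% of variable reads, against 5 of 53 single-class letter_number cells (9.43%), and 7 of 7 a second light-chain variable gene, against 7 of 53. They also had more other genes with a read, 5469 against 4395 at the median. Index misassignment is argued against, since the second-class reads were at least 2.93% of those in the cells sharing the letter or number, far above the 0.0467% typical of variable genes. Capture of 2 cells together may account for 6 of the 7 cells, and B4, whose second variable gene held 9.28%, stays open.

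The variable genes Ighv11-2 and Igkv14-126 were the most-read pair in 9 cells, a signal outside the class comparisons.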

How the results depend on the processing

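Equal weight for the title forms, thinning to 250000 reads, the read spill limit, leaving out Jchain, leaving out cells with a second variable gene, leaving out the decimal cell 22.3 or each IgG-class cell in turn, and all alternatives on the other lists were chosen after seeing the data. A value counts as kept if it stayed within its counting interval or, as mean log2, if it kept its sign. Intervals are wide at these cell numbers. For a list the interval treats the mean share as the share of 1 gene, so it is not the error of a list mean. Adhesion for IgG minus IgM counts as kept at 11.7 points in decimal cells against -3.13 pooled, so the kept counts are a weak check. By these rules 50 of 51 niche list values were kept for IgG minus IgM, with 1 outside, 51 of 51 for IgA minus IgM and 50 of 51 for IgA minus IgG. In percentage points, survival receptors ranged from -12.3 to -1.88 for IgG minus IgM and from -17.4 to -6.86 for IgA minus IgM, and adhesion molecules from -11.9 to -4.27 for IgA minus IgG. Ranges that crossed 0 were -6.03 to 11.7 (adhesion, IgG minus IgM), -14.5 to 5.83 (adhesion, IgA minus IgM), -14.6 to 5.42 (survival, IgA minus IgG), and -3.45 to 49.05, -4.51 to 5.93 and -7.89 to 3.5 (chemokine receptors, IgG minus IgM, IgA minus IgM and IgA minus IgG). The value 49.05 came from the filter on genes in at least 10% of cells, which left Cxcr4 alone. As mean log2, chemokine receptors moved to 0.068 for IgA minus IgG, and for IgG minus IgM the TGF-beta list to -0.048 and autophagy to -0.014; the cause was not tested. Leaving out each IgG-class cell in turn gave proliferation differences of 19.3 to 26.9 points for IgG minus IgM. Class sizes moved with the title form, to 61.7% IgM and 5% IgA in letter_number cells and to 10.3% IgM, 79.5% IgA and 10.3% IgG in decimal cells. Of named gene values, 980, 804 and 1222 were kept (IgG minus IgM, IgA minus IgM, IgA minus IgG), 39, 57 and 45 moved and 1, 23 and 8 reversed. The cause of these changes was not tested. The kept counts, also those of the niche lists, include settings that could not move a value. The stricter cell filter and the 95% class share changed no cell in the shares. The 10% gene filter left single named genes untouched, and leaving out cell 22.3 could not alter IgA minus IgM. Reversed means a changed sign where the counting interval of the main value excluded 0. Other genes can change sign and count as moved or kept. With detection at 1 read, Ms4a1 reversed to 5.95 points for IgG minus IgM and Sqstm1 to -7.33 for IgA minus IgG. In letter_number cells alone, with 3 IgA-class cells, IgA minus IgM reversed to -9.38 for Nrip1 and Tigit, -7.29 for Glipr1, 40.6 for Ikzf1, 18.8 for Ikzf3, 12.5 for H2-Ab1, 3.13 for Slc3a2 and 16.7 for Atg5, and IgA minus IgG to 11.1 for H2-Aa and 22.2 for Atg5. In decimal cells alone, with 3 IgM-class and 3 IgG-class cells, IgA minus IgM reversed to -4.55 for Cd69, -27.3 for Jund, -3.03 for Atxn1, 9.09 for Cxcr4, Ern1 and Lamp1, 40.9 for Cd47, 18.2 for Ikzf1, -9.09 for Klf6 and 30.3 for Gabarap. IgA minus IgG reversed there to 13.6 for Pcna, 9.09 for Mcm6 and Lamp1, -3.03 for Ctla4 and 7.58 for Ctsd. With equal weight for the title forms, IgA minus IgM reversed to -11.0 for Jund, 14.7 for Cd47, 29.4 for Ikzf1, -0.9 for Klf6 and 15.2 for Gabarap. The planned agreement between title forms needed 5 cells of each class per form and could not be run; the agreement given used 3. No paired analysis was possible because the labels give 1 group and no replicate shared between groups. Depth limits the shares to 79 cells and to genes above about 5 of 630000 reads.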

Other observations

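The test of proliferation against more genes per cell and the count of cells with 15 or more proliferation genes were chosen after their results were seen, and thinning to 250000 reads, the read spill limit the removal of cells with a second variable gene and leaving out cell 22.3 were added after seeing the data.

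The antibody repertoire was broad, with 76 pairs of most-read heavy and light variable genes, 39 heavy and 44 light variable genes. Of these, 12 pairs recurred, in 35 cells. Ighv11-2 with Igkv14-126, a pair known from B-1 cells that bind phosphatidylcholine, was found in 9 cells, all in the IgM class, of which 8 were letter_number and 1 decimal. Ighv3-6 with Igkv8-30 was found in 4 IgA-class decimal cells, and Ighv1-55 with Igkv12-89 and Ighv9-3 with Igkv3-5 in 3 IgM-class cells each. Lambda light chains led in 5 of 99 cells (5.05%, 1.66% to 11.4%). Variable genes of 1 family share sequence, so single assignments are uncertain, and no junction sequence was analysed here.

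Reads of Xist, transcribed from the inactive X chromosome, reached 20 in 42 of 60 letter_number cells and 5 of 39 decimal cells. Y-linked genes reached 20 reads in 0 letter_number and 3 decimal cells, and 31 decimal cells had neither.

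Proliferation genes were concentrated in a few cells. With all cells thinned to 250000 reads, 15 or more of the 31 genes were detected in 5 of 17 IgG-class cells (29.4%, 10.3% to 55.96%), 0 of 41 IgM-class cells (which allows up to 7.32%), 0 of 34 IgA-class cells (up to 8.82%) and 2 of 7 unclassed cells. More genes of any kind per IgG-class cell is argued against as the whole cause, since the list lay at percentile 100 of matched random lists within letter_number cells, 27.3 points against a random median of 3.84. Index misassignment is argued against too, since 103.654% of the difference (28.3 points) was left with the read spill limit. Without cells carrying a second heavy-chain variable gene the pooled proliferation difference was 26.2 points, and without the decimal cell 22.3 it was 21.4. No biological explanation was tested, and the labels leave open whether the 5 cells came from 1 animal.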
